A study of Mus musculus with 6 samples.

How the data were processed

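Total RNA of 6 mouse iPS cell lines was hybridised to Affymetrix whole-transcript arrays, 1 array per line. Per the labels' protocols, retroviruses for 4 reprogramming factors were given with an shRNA against luciferase (control clones 2, 3 and 4) or against E-cadherin (shECAD clones 4, 8 and 9). The cells were split onto feeders on day 6, colonies were picked on day 14, feeder cells were removed before Trizol extraction, and biotin-labelled cDNA was made from 100 ng of RNA, per the labels.

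The deposited values are log2 expression values per probeset, for which the authors used RMA and Partek, per the submitters' processing notes. Versions, settings and the genome build are not given in the sources used here. The deposited table holds 28853 probesets with values from 0.949 to 14.044, and 679 probesets have the same values as another probeset. The arrays' medians (5.11 to 5.30) and SDs (2.11 to 2.26) are close but not equal, and the values were used as deposited.

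Probesets were named through the platform annotation, in which 21789 have 1 gene symbol, 1621 have several and 5443 have none here. Of those with 1 symbol, 21698 matched a RefSeq gene table (assembly GRCm38.p6, used for names only) by their Entrez identifier and 91 kept the annotation's symbol, and 0 symbols changed. Probesets with several genes were left out of the comparison by gene and tested in an alternative. The probeset with the highest mean over the 6 arrays stood for each of the 999 genes with several, which left 19938 genes, with no filter on dim probesets.

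The 2 groups were compared with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, with no covariate and each clone as 1 replicate. P-values were adjusted by the method of Benjamini and Hochberg over all genes, and an adjusted p below 0.05 was a call. Fold changes are shECAD minus control on the log2 scale. Cdh1 was also compared by a two-sided exact permutation test over the 20 labellings of 3 clones against 3, whose smallest p is 0.1. The 22 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. They cover the pluripotency network, epithelial junctions, mesenchymal transition, fibroblast and feeder markers, other cadherins and catenins, Wnt targets, LIF and STAT3 signalling, FGF and ERK targets, Nodal and primed epiblast, endoderm, mesoderm, neural, trophoblast, endothelial and blood, germline, 2-cell-like, imprinted, Y-linked, p53, hypoxia, interferon, and actin genes. Of the fibroblast list's 23 measured members, 1 (Cdh11) is in another list and 17 lie above the median gene level in the control clones. Counts adjusted over the list alone use the members of 1 list. Distances between clones were Euclidean over all 19938 genes.

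The named genes follow a rule also fixed before the data were examined. They are Cdh1 and the genes of the 4 reprogramming factors, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (predicted loci left out), and in each list up to 5 called members by size or else the 3 with the largest change. Other genes in the text were chosen after their values were seen, as members of these lists.

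The alternatives were centring each array on its median, quantile normalization, only genes at or above the median level, the mean of a gene's probesets, an intensity trend with a robust prior, array quality weights, no variance moderation, every probeset on its own, an adjusted p of 0.1, another distance, the other set tests, and leaving out each clone. A term for high Y-linked genes (Eif2s3y above 6.5) and the mean of the fibroblast list were added as covariates after the data were seen.

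The fit was tested on simulated data for the comparison of shECAD with control, over 19938 genes of which 50 were changed at each size. It recovered 8% of changes of 0.5 on the log2 scale, 90% of changes of 1 and 100% of changes of 2 and of 3, and called 10 unchanged genes. A simulated shift of 1 list was called, along with 2 of 21 lists that had not been shifted. Figures were drawn with matplotlib 3.10.9.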

Results

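The series measured mRNA in 6 mouse induced pluripotent stem (iPS) cell lines, each grown from 1 colony. The starting cells were mouse embryonic fibroblasts of the OG2 strain, which carries a green fluorescent reporter under Oct4 control. The fibroblasts received retroviruses for the reprogramming factors Oct4, Sox2, Klf4 and c-Myc together with a short hairpin RNA (shRNA). In the 3 control clones, numbered 2, 3 and 4, the shRNA was directed against luciferase, a gene that mouse cells lack. In the 3 shECAD clones, numbered 4, 8 and 9, it was directed against E-cadherin, the product of Cdh1 and the main adhesion molecule of epithelial and pluripotent cells. The cells were moved onto a feeder layer on day 6 after infection and the colonies were picked on day 14. Each clone gave 1 whole-transcript array, so that n = 3 clones per group throughout, and this number limits the precision. The labels describe separate cell lines but no separate infections, so the p-values measure the spread between clones. The median log2 value lay between 5.11 and 5.30 on the 6 arrays and the SD between 2.11 and 2.26. The comparison of the 2 groups asks how iPS lines made with E-cadherin shRNA differ from control lines.

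Cdh1 mRNA, the target of the shRNA, was lower in each shECAD clone than in any control clone. Its probeset (10575052) read 9.18, 9.60 and 9.07 in control clones 2, 3 and 4 and 6.75, 6.92 and 7.81 in shECAD clones 4, 8 and 9. The group means were 9.28 ± 0.28 and 7.16 ± 0.57 (SD, n = 3 each). The log2 fold change was -2.13 ± 0.27 (SE), with a limma adjusted p of 0.00683. On the linear scale the shECAD mean was 22.9% of the control level, with a 95% confidence interval from 15.2% to 34.4%. A two-sided exact permutation test of the difference gave p = 0.1, the smallest p that 3 clones against 3 can give. In a fit without variance moderation the fold change was the same and the limma adjusted p was 0.194. With the mean of the fibroblast and feeder list as a covariate, the log2 fold change was -2.23 ± 0.59 (SE) and the limma adjusted p was 0.998.

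The mRNAs of the reprogramming factors did not pass the test. The log2 fold change was -0.05 ± 0.18 (SE) for Pou5f1, which encodes Oct4, -0.39 ± 0.27 for Sox2, -0.38 ± 0.24 for Klf4 and 0.27 ± 0.31 for Myc, with limma adjusted p-values of 0.918, 0.504, 0.438 and 0.705. Pou5f1 read 10.64 ± 0.12 (SD) in the control clones and 10.59 ± 0.27 in the shECAD clones. With 1 clone left out, the change of Pou5f1 ran from -0.14 (without shECAD clone 4) to 0.11 (without shECAD clone 9), that of Sox2 from -0.62 to -0.05 (without the same clones), that of Klf4 from -0.67 (without control clone 3) to -0.15 (without control clone 4) and that of Myc from -0.13 (without control clone 4) to 0.48 (without control clone 3). Pou5f1 also turned after quantile normalization (0.036) and with array weights (0.074). With the fibroblast and feeder list mean as a covariate the changes were -0.32 for Pou5f1, 0.13 for Sox2, 0.12 for Klf4 and -0.80 for Myc. Whether these probesets also read viral transcripts was not tested.

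**Figure D1:**
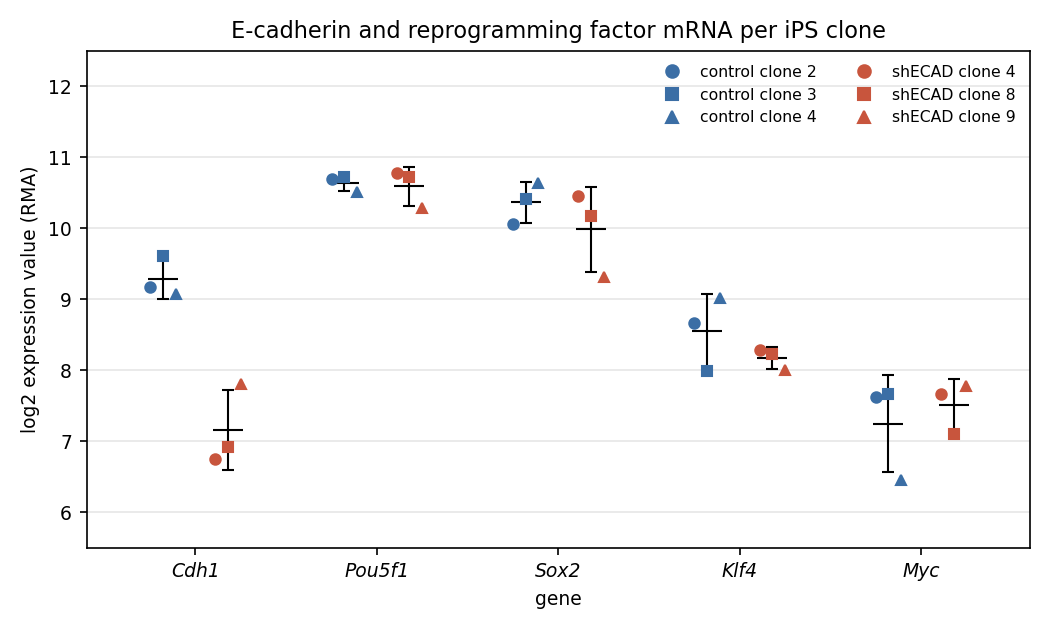
Log2 expression values (vertical axis) of Cdh1, Pou5f1, Sox2, Klf4 and Myc in the 3 control and 3 shECAD clones; points are clones, horizontal bars are group means and whiskers are SD. The Cdh1 values of the shECAD clones reach at most 7.81 and those of the control clones start at 9.07, while the groups lie closer together for the other genes.

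Of the 29 measured genes of the pluripotency network list, 28 did not pass the test and 1, the DNA demethylation enzyme gene Tet1, fell by 0.79 on the log2 scale (limma adjusted p = 0.0462). Adjusted over the list alone, 8 members were lower and 0 higher. Nanog, a core pluripotency factor, had a log2 fold change of 0.04 and Zfp42 one of 0.13, and neither passed the test. The list as a whole had a median log2 fold change of -0.42 and lay lower in the set test camera (adjusted p = 2.02e-05, and adjusted p = 0.328 with an estimated correlation). Without shECAD clone 9 the mean log2 fold change of the list was -0.17 instead of -0.38. Tet1 lost its call when any 1 of the 6 clones was left out, with adjusted p-values up to 0.162, and after quantile normalization. Among 14 genes of LIF and STAT3 signalling, which maintains mouse pluripotent cells, Lifr, the LIF receptor gene, had a log2 fold change of -1.002 and Gbx2 one of -0.65 (limma adjusted p = 0.0176 and 0.0465). Lifr lost its call without control clone 4 (adjusted p = 0.0734), and Gbx2 lost it when any clone was left out, with adjusted p-values up to 0.14, and with high Y-linked genes as a covariate (0.0587). Adjusted over the list alone, 3 members were lower and 1 higher. The list lay lower (camera adjusted p = 0.0158, and adjusted p = 0.273 with an estimated correlation). This call ended after quantile normalization (adjusted p = 0.0865), among brighter genes alone (0.109), without control clone 2 (0.068) and without shECAD clone 9 (0.0508).

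Across the genome, 623 of 19938 genes (3.12%) differed between the groups at a limma adjusted p below 0.05, of which 378 were higher and 245 lower in the shECAD clones. At least a 2-fold change was seen in 289 of them, 195 higher and 94 lower. The 10 largest rises were in Acta2, Thbs1, Tnc, Kcnma1, Klhl13, Mgp, Timp3, Fndc3c1, Peg10 and Slc40a1. Acta2, which encodes smooth muscle actin, rose 10.7-fold from 6.75 ± 1.23 (SD) to 10.17 ± 0.09 (log2 fold change 3.42 ± 0.46 SE, adjusted p = 0.00812). Thbs1, the gene of the matrix protein thrombospondin 1, rose 8.48-fold (3.08 ± 0.27, adjusted p = 0.00282), and Tnc, the gene of tenascin C, 7.58-fold (2.92 ± 0.49, adjusted p = 0.0153). Without control clone 2 the log2 fold change was 4.08 for Acta2 and 3.60 for Tnc, and without control clone 4 it was 2.33 for Tnc. Mgp and Timp3, which encode a matrix protein and a metalloproteinase inhibitor, rose 6.00-fold and 5.98-fold, and the iron exporter gene Slc40a1 rose 5.17-fold. The potassium channel gene Kcnma1 rose to 5.90 ± 0.997 (SD) from 3.21 ± 0.43, a level below the 25th percentile of each control array (3.73 to 3.91), so that the size of its change is not given as a fold. Klhl13 rose 6.17-fold, Fndc3c1 5.53-fold and Peg10 5.17-fold. The 10 largest falls were in Dpp4, Hal, Rbm44, Cdh1, Tex11, Nlrp4f, Obox6, Dazl, Rnf17 and Cspg4b. Dpp4, a cell surface peptidase gene, had a log2 fold change of -2.47 ± 0.22 (SE, adjusted p = 0.00282). Hal, the gene of a histidine-degrading enzyme, had one of -2.42 ± 0.17 (adjusted p = 0.000638). The log2 fold changes of the remaining falls were -2.13 for Rbm44, -2.10 for the meiosis gene Tex11, -1.91 for Nlrp4f, -1.89 for Dazl, -1.87 for Rnf17 and -1.86 for Cspg4b. The oocyte homeobox gene Obox6 fell from 5.39 ± 0.46 (SD) to 3.49 ± 0.74, a mean below the 25th percentile of each shECAD array (3.84 to 4.01), and the size of its change is not given either. Whether the places of Kcnma1 and Obox6 among the largest changes depend on these low levels was not tested. Among these 20 genes, 6 lost their call when a clone was left out. Tnc, Klhl13, Fndc3c1 and Obox6 reached adjusted p-values up to 0.0641, 0.0567, 0.0675 and 0.0775, all without shECAD clone 8. Tnc also lost its call without shECAD clone 4, Fndc3c1 without control clone 4, and Obox6 without control clone 3, control clone 4 or shECAD clone 9. Tex11 lost its call without control clone 3 (0.074), control clone 4 or shECAD clone 4, and Nlrp4f without any 1 control clone (up to 0.102 without control clone 4) or shECAD clone 4. Tnc, Tex11 and Nlrp4f also lost theirs under an intensity trend with a robust prior (0.0724, 0.058 and 0.0513), and Nlrp4f after quantile normalization (0.0514).

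The groups did not overlap in 4708 genes, or 23.6%, where chance gives 10%. After each array was centred on its median, 681 genes were called and the split turned to 298 higher and 383 lower. With 1 clone left out, the count was 543 without control clone 2, 271 without control clone 3, 146 without control clone 4, 231 without shECAD clone 4, 156 without shECAD clone 8 and 290 without shECAD clone 9. With the mean of the fibroblast and feeder list as a covariate, limma called 0 genes, and 839 genes had an unadjusted p below 0.05. This covariate lies apart between the groups, and the median SE over all genes was 0.394 with it and 0.176 without it.

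Of 23 measured fibroblast and feeder cell genes, 14 rose in the shECAD clones and 0 fell, and adjusted over the list alone 20 rose. Lox, which encodes a collagen cross-linking enzyme, rose 5.11-fold (log2 fold change 2.35 ± 0.30 SE, limma adjusted p = 0.007), and Postn, the gene of periostin, rose 4.79-fold (2.26 ± 0.23, adjusted p = 0.00282). The type I collagen gene Col1a1 rose 3.92-fold from 7.84 ± 0.85 (SD) to 9.81 ± 0.10, and Ccdc80 rose 4.13-fold. The proteoglycan genes Lum and Dcn and the receptor gene Pdgfra did not pass the test, with log2 fold changes of -0.23, 0.48 and 0.38. The median of the list was 1.07 (camera adjusted p = 1.23e-18, and adjusted p = 0.273 with an estimated correlation). The mean log2 level of the list was 6.68, 6.29 and 5.61 in control clones 2, 3 and 4 and 7.31, 7.64 and 7.36 in shECAD clones 4, 8 and 9. The clones were kept on feeder cells, which were removed before RNA extraction per the labels. The list held 8 calls without control clone 3 or without shECAD clone 4, 9 without control clone 4 and 4 without shECAD clone 8. Col1a1 and Cdh11 lost their calls without shECAD clone 8 (adjusted p = 0.0661 and 0.0527).

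Some genes of mesenchymal transition and of the contractile and adhesive cytoskeleton rose beside the fibroblast list, whose mean log2 level lay between 5.61 and 6.68 in the control clones and between 7.31 and 7.64 in the shECAD clones. In the mesenchymal list 11 of 21 members rose and 0 fell, and adjusted over the list alone 16 rose. Besides Acta2, the smooth muscle genes Tagln and Cnn1 rose 3.31-fold and 2.89-fold (limma adjusted p = 0.00293 and 0.0119). Prrx1, a transcription factor gene of connective tissue, rose 2.94-fold and Tgfb3 rose 2.17-fold (adjusted p = 0.0339 and 0.0185). The transition regulators Snai1, Zeb1 and Zeb2 had log2 fold changes of 0.43, -0.10 and 0.41 and did not pass the test. Nor did Twist1, with 0.58 (limma adjusted p = 0.0811). The regulators Snai2, Twist2 and Foxc2 did pass, with log2 fold changes of 0.98, 0.89 and 0.69 (limma adjusted p = 0.0347, 0.0339 and 0.0491). All 3 lost their calls without control clone 4, shECAD clone 4 or shECAD clone 8, where the calls left in the list were Acta2, Tagln and Cnn1. Vim, another member, had a log2 fold change of 0.85 and did not pass (limma adjusted p = 0.119). The median of the list was 0.83 (camera adjusted p = 1.13e-14, and adjusted p = 0.273 with an estimated correlation). In the list of actin and focal adhesion genes, 10 of 23 members rose and 1 fell, and adjusted over the list alone 13 rose and 1 fell. Lpp rose 3.85-fold, the caldesmon gene Cald1 2.84-fold and the tropomyosin gene Tpm1 2.34-fold (adjusted p = 0.0114, 0.0123 and 0.0119), and the caveolin gene Cav1 rose 2.52-fold and Ankrd1 2.42-fold (adjusted p = 0.0287 and 0.0302). The member that fell was the integrin gene Itga6, by 0.84 on the log2 scale, and it was no longer called without any clone other than control clone 2 or with high Y-linked genes as a covariate. The median was 0.61 (camera adjusted p = 1.3e-06, and adjusted p = 0.273 with an estimated correlation). With the fibroblast list mean as a covariate, neither list was called (adjusted p = 0.0538 and 0.187). The mean over clones went from 0.92 (95% interval 0.44 to 1.41) to 0.28 (-0.05 to 0.61) for the mesenchymal list and from 0.56 (0.26 to 0.86) to 0.17 (-0.12 to 0.47) for the actin list. Without shECAD clone 8 the calls numbered 3 in the mesenchymal list and 2 in the actin list. They numbered 3 and 3 without control clone 4, 4 and 5 without control clone 3, 3 and 4 without shECAD clone 4, and 5 and 5 without shECAD clone 9. The log2 fold change of Lpp was 1.12 when its probesets were averaged. Cald1 lost its call without shECAD clone 8 (adjusted p = 0.0536). Prrx1, Cav1 and Ankrd1 lost theirs with any clone but control clone 2 left out (up to 0.106, 0.0865 and 0.0987, each without shECAD clone 8), and Tgfb3 did so with control clone 3, control clone 4, shECAD clone 4 or shECAD clone 8 left out (up to 0.0784 without control clone 4). Ankrd1 also lost its call after quantile normalization.

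Several epithelial genes other than Cdh1 were higher in the shECAD clones. Of 32 measured members of the list of epithelial junctions and their regulators, 7 rose and 2 fell, and adjusted over the list alone 11 rose and 2 fell. The keratin genes of simple epithelia rose most: Krt18 rose 4.53-fold, Krt19 4.25-fold and Krt8 3.63-fold (limma adjusted p = 0.0115, 0.0123 and 0.0255). Dsp, which encodes the desmosomal protein desmoplakin, rose 2.74-fold (log2 fold change 1.46 ± 0.18 SE, adjusted p = 0.00617). Cdh1 and Spint1 fell, Spint1 by 0.88 on the log2 scale. Epcam, another adhesion gene of epithelial and pluripotent cells, had a log2 fold change of -0.15 and did not pass the test. The median of the list was 0.45 (camera adjusted p = 2.1e-06, and adjusted p = 0.273 with an estimated correlation). In the fit with the fibroblast list mean as a covariate, camera still called the list (adjusted p = 1.88e-06), while 0 members were called. There the mean over clones went from 0.50 (95% interval 0.07 to 0.93) to 0.62 (-0.57 to 1.81). Krt8 lost its call without control clone 3 or 4, with an adjusted p of 0.0784 without the latter. The 7 rises became 4 without control clone 3, control clone 4 or shECAD clone 4, and the 2 falls became 1, Cdh1, without control clone 4, shECAD clone 4 or shECAD clone 8. Among 24 genes of other cadherins and catenins, 2 rose and 0 fell, both over all genes and adjusted over the list alone. They were Cdh11, the cadherin of fibroblasts and bone (3.83-fold, adjusted p = 0.012), and Cdh2, which encodes N-cadherin (1.93-fold, adjusted p = 0.0298). The catenin genes Ctnnb1, Ctnna1 and Ctnnd1 had log2 fold changes of 0.06, -0.05 and 0.05. The list lay higher, with a median of 0.27 (camera adjusted p = 0.00272, and adjusted p = 0.273 with an estimated correlation), but not among brighter genes alone (median 0.036, adjusted p = 0.132) or with the fibroblast list mean as a covariate (median 0.25, adjusted p = 0.133), where the mean over clones was 0.19 with a 95% interval from -0.32 to 0.70, against 0.29 and an interval from 0.09 to 0.48 without the covariate. This list had a median of 0.17 after median centring and 0.16 after quantile normalization. The fit of brighter genes alone held 11 of its 24 members. Cdh11 lost its call without shECAD clone 8 (adjusted p = 0.0527), and neither gene was called there. Cdh2 lost its call with any clone but control clone 3 left out, up to an adjusted p of 0.116 without control clone 4, and after quantile normalization. Of 17 Wnt target genes, 1 fell, the feedback inhibitor gene Notum, by 0.87 (adjusted p = 0.0278), and 0 rose, whereas the median of the list was 0.28 and camera placed the list higher (adjusted p = 0.0227, and adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone, 1 rose and 1 fell. The call of the Wnt list ended without control clone 4 (0.0816), without shECAD clone 9 (0.0879) and among brighter genes alone (0.387, with 8 of 17 members). It also ended with the fibroblast list mean as a covariate (0.516), where the mean over clones went from 0.19 (95% interval -0.04 to 0.42) to 0.10 (-0.52 to 0.72). Notum lost its own call with any clone but control clone 3 left out, up to 0.112 without control clone 4, and without control clone 2 the list held 1 rise and 0 falls.

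Of 19 measured germline genes, 5 fell in the shECAD clones and 0 rose, and adjusted over the list alone 7 fell. Dazl, an RNA-binding protein gene of germ cells, went from 6.51 ± 0.49 (SD) to 4.62 ± 0.54, a 3.71-fold fall (limma adjusted p = 0.0123). Stra8, which marks entry into meiosis, fell 3.22-fold (adjusted p = 0.00414), and the synaptonemal complex gene Sycp1 fell 3.11-fold (adjusted p = 0.0305). Ddx4, the mouse vasa gene, fell 2.18-fold, and Piwil2, a gene of the piRNA pathway, 2.11-fold (adjusted p = 0.0318 and 0.0295). Sycp3, Dmrt1, Brdt and Tdrd1 had log2 fold changes of -0.16, -0.06, -0.03 and 0.01 and did not pass the test. The median of the list was -0.70 (camera adjusted p = 4.95e-07, and adjusted p = 0.273 with an estimated correlation). The germline median was -1.30 with the fibroblast list mean as a covariate, where the mean over clones was -1.09 with a 95% interval from -3.01 to 0.83. The mean log2 level of the list was 5.66, 6.01 and 5.51 in control clones 2, 3 and 4 and 5.17, 5.22 and 4.56 in shECAD clones 4, 8 and 9. The 5 calls became 2 without control clone 2 or control clone 3 and 3 without control clone 4, shECAD clone 4 or shECAD clone 9. Dazl and Stra8 stayed called with any clone left out, while Sycp1 lost its call without any 1 control clone (adjusted p up to 0.0923 without control clone 4). Ddx4 lost its call with any clone but shECAD clone 8 left out, and Piwil2 without control clone 2, control clone 3, shECAD clone 4 or shECAD clone 9, up to 0.0987 and 0.0778, both without shECAD clone 4.

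**Figure D2:**
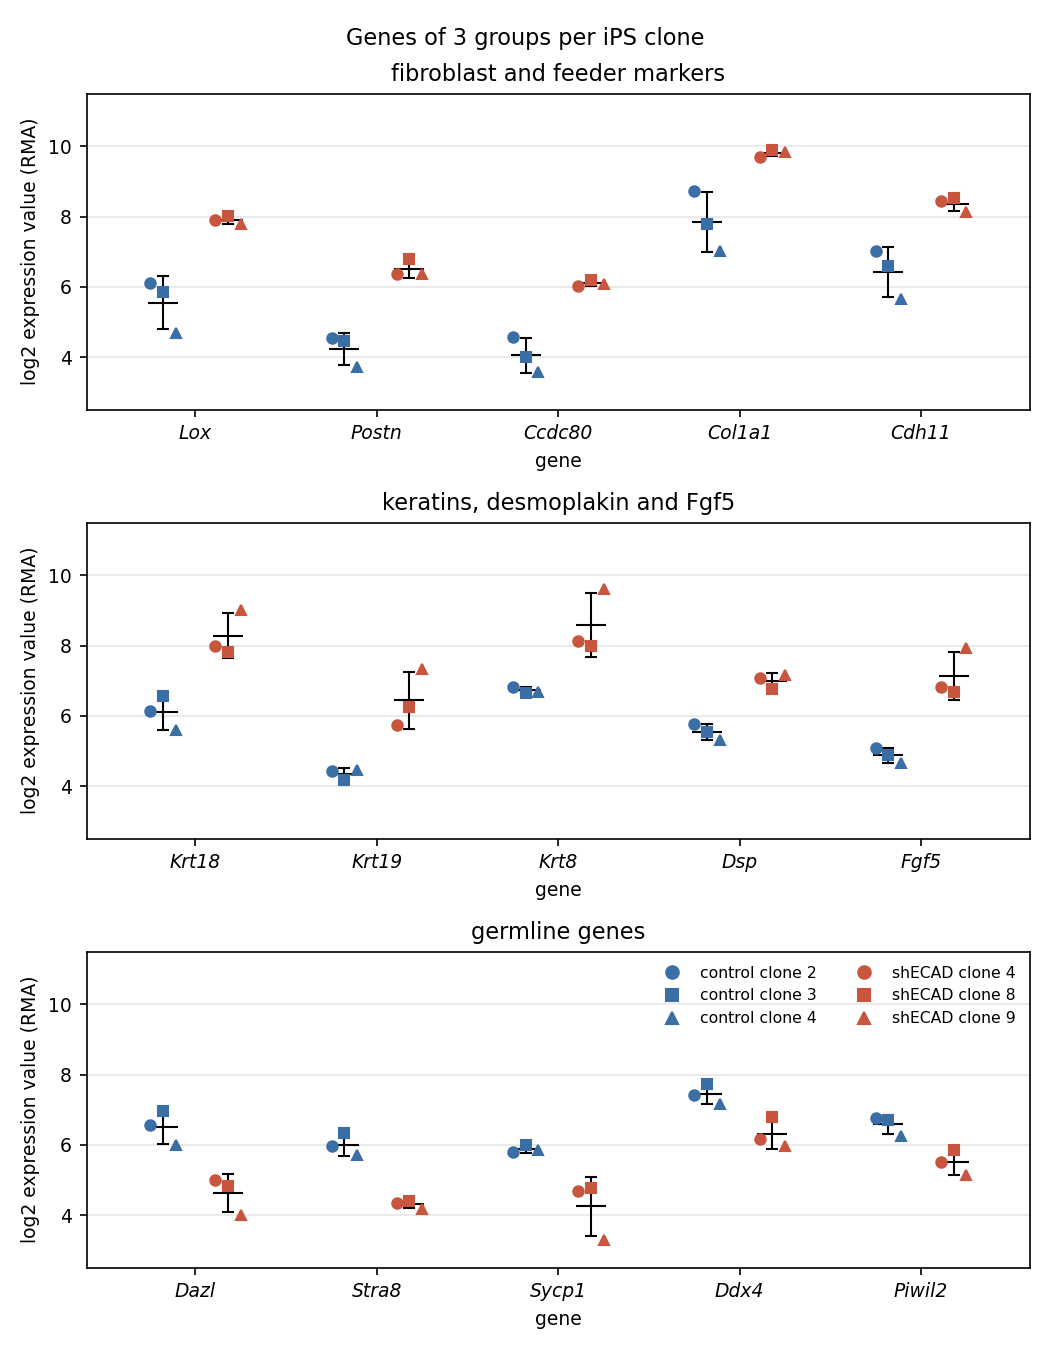
Log2 expression values (vertical axis) per clone of 5 fibroblast and feeder markers, of 3 keratin genes with Dsp and Fgf5, and of 5 germline genes; points are clones, horizontal bars are means and whiskers are SD over 3 clones. In each of the 15 genes all shECAD clones lie on one side of all control clones, higher in the upper and middle panels and lower in the bottom panel. The 15 were chosen as called genes, and no called gene had overlapping groups, so this separation follows from the choice.

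In the shECAD clones 7 of 19 genes of hypoxia and glycolysis rose and 0 fell, and adjusted over the list alone 14 rose and 1 fell. P4ha1, a collagen prolyl hydroxylase gene, rose 2.28-fold (limma adjusted p = 0.007), the glycolytic enzyme genes Pfkl and Pgk1 had log2 fold changes of 0.98 and 0.92 (adjusted p = 0.0179 and 0.0176), and Bnip3, Ddit4 and Ndrg1 rose 2.60-fold, 2.17-fold and 2.09-fold (adjusted p = 0.0467, 0.0326 and 0.0319). Vegfa and Car9 had log2 fold changes of 0.17 and 0.08 and did not pass the test. The median of the list was 0.78 (camera adjusted p = 2.34e-07, and adjusted p = 0.273 with an estimated correlation). In the fit with the fibroblast list mean as a covariate, camera still called the list (adjusted p = 2.87e-09), while 0 members were called. There the mean over clones went from 0.56 (95% interval 0.25 to 0.87) to 0.83 (0.15 to 1.5). The 7 calls became 3 without control clone 4 or shECAD clone 9 and 1 without shECAD clone 8. Bnip3, Ddit4, Ndrg1 and Pfkl lost their calls with some clones left out, up to adjusted p-values of 0.127, 0.103, 0.116 and 0.0687, the former pair without shECAD clone 8 and the latter without control clone 4. Bnip3 also lost its call after median centring, under an intensity trend with a robust prior and when its probesets were averaged (0.0554, 0.0653 and 0.0566). Of 22 imprinted genes, which are expressed from 1 parental allele, 4 rose and 0 fell, and adjusted over the list alone 11 higher and 0 lower. Peg10 rose 5.17-fold (adjusted p = 0.00282), and Ndn, Dlk1 and Impact rose 1.98-fold, 1.96-fold and 1.83-fold (adjusted p = 0.0205, 0.0195 and 0.0302). The median was 0.69 (camera adjusted p = 2.41e-06, and adjusted p = 0.122 with an estimated correlation), and it was 0.22 with the fibroblast list mean as a covariate, where the mean over clones went from 0.57 (95% interval 0.39 to 0.75) to 0.45 (0.01 to 0.89). The fibroblast list rose beside it, with a median of 1.07. The 4 rises became 2 without control clone 3 or shECAD clone 4 and 1, Peg10, without shECAD clone 8. There were 2 rises and 1 fall without shECAD clone 9, 6 rises and 1 fall without control clone 2, and 8 rises with array weights. Ndn, Dlk1 and Impact reached adjusted p-values of 0.0767 without shECAD clone 8 and 0.0783 and 0.127 without control clone 4. In the list of p53 and cell cycle arrest, 1 of 16 genes rose, the death receptor gene Fas (1.97-fold, adjusted p = 0.0412), and 0 fell, while adjusted over the list alone 5 rose and 1 fell. The list lay higher, with a median of 0.35 (camera adjusted p = 0.0158, and adjusted p = 0.273 with an estimated correlation), but not without shECAD clone 8 (adjusted p = 0.147) or with the fibroblast list mean as a covariate (0.652), where the mean over clones went from 0.23 (95% interval 0.02 to 0.44) to 0.06 (-0.42 to 0.55). The p53 list held 3 rises among brighter genes alone and 4 with array weights. Fas lost its call after median centring or quantile normalization (0.0524 and 0.0798), with high Y-linked genes as a covariate (0.0555) and with any clone but control clone 2 left out, up to 0.15 without control clone 4.

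Among lineage genes, Fgf5, a marker of the primed epiblast, rose 4.81-fold from 4.87 ± 0.22 (SD) to 7.14 ± 0.68 (limma adjusted p = 0.007). It was the single call among 15 genes of Nodal signalling and primed epiblast, where adjusted over the list alone 3 rose and 1 fell. That list held 2 rises without control clone 3 or shECAD clone 4 and 1 with any other clone left out. It held 3 among brighter genes alone. Nodal and Otx2 had log2 fold changes of 0.01 and 0.70 and did not pass the test. This list lay higher (median 0.26, camera adjusted p = 0.0334, and adjusted p = 0.273 with an estimated correlation), but not without control clone 2 (adjusted p = 0.0891), control clone 4 (0.0787) or shECAD clone 9 (0.064). It was not called with the fibroblast list mean as a covariate either (0.11), where the mean over clones was 0.40 with a 95% interval from -0.78 to 1.57, against 0.42 and an interval from 0.01 to 0.83 without the covariate. Its median was 0.11 without shECAD clone 9, 0.53 without control clone 3 and 0.17 after median centring. Of 16 FGF and ERK targets, the phosphatase gene Dusp4 rose 2.77-fold (adjusted p = 0.00948), 0 fell, and the list was not called (camera adjusted p = 0.509); adjusted over the list alone 1 rose and 1 fell. In the list of primitive and visceral endoderm, the basement membrane collagen genes Col4a2 and Col4a1 rose 2.01-fold and 1.75-fold (adjusted p = 0.0164 and 0.0467) of 20 members, 0 fell, and adjusted over the list alone 4 rose. The endoderm regulators Gata4, Gata6 and Sox17 had log2 fold changes of 0.37, 0.59 and 0.21 and did not pass the test. That list lay higher (median 0.29, camera adjusted p = 0.00396, and adjusted p = 0.417 with an estimated correlation) but not without control clone 3 (0.0511), and without control clone 4 or shECAD clone 8 it held 0 calls, Col4a2 reaching 0.0745 and Col4a1 0.168 without control clone 4. Col4a1 also lost its call after median centring or quantile normalization (0.0524 and 0.0527) and with high Y-linked genes as a covariate (0.0671). For the endoderm list the median was 0.18 without control clone 3, 0.15 without shECAD clone 9 and 0.49 among brighter genes alone (12 of 20 members). It was not called with the fibroblast list mean as a covariate (adjusted p = 0.652), where the mean over clones went from 0.28 (95% interval -0.20 to 0.76) to 0.05 (-1.23 to 1.33). In the list of 17 primitive streak and mesoderm genes, 0 passed the test over all genes and 2 were higher adjusted over the list alone. The largest log2 fold changes were 0.80 for Mixl1, 0.70 for Kdr and 0.70 for Wnt8a, and Mixl1 had 0.22 without shECAD clone 9 and 0.42 with array weights. The list lay higher (median 0.22, camera adjusted p = 0.00272, and adjusted p = 0.366 with an estimated correlation). It was not called among brighter genes alone (0.375), but that fit held only 2 of the 17 members and cannot speak for the list. Its median was 0.087 without control clone 3, 0.12 without shECAD clone 9, 0.35 without control clone 2 or shECAD clone 8, 0.13 after median centring or quantile normalization, and 0.40 with the fibroblast list mean as a covariate. Of 16 trophoblast genes, 1 rose, Peg10, 0 fell, and adjusted over the list alone 2 rose. The trophoblast regulator Cdx2 had a log2 fold change of 0.07. The list lay higher (median 0.23, camera adjusted p = 0.0123, and adjusted p = 0.273 with an estimated correlation) but not without shECAD clone 4 (0.0912), where the median was 0.12. The trophoblast median was 0.14 after median centring, 0.13 after quantile normalization, 0.47 among brighter genes alone (6 of 16 members) and 0.39 with the fibroblast list mean as a covariate. Of 19 neural and ectoderm genes, the intermediate filament gene Nes rose 2.34-fold (adjusted p = 0.0302) and 0 fell, with 1 higher and 1 lower adjusted over the list alone. The list was not called (camera adjusted p = 0.509), and its median turned from 0.12 to -0.0081 after quantile normalization, -0.033 without control clone 3 and -0.02 among brighter genes alone (5 of 19 members). Nes lost its call without control clone 2, control clone 4, shECAD clone 8 or shECAD clone 9, up to 0.0992 without control clone 4.

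Few or no genes passed the test in the remaining lists. Of 15 endothelial and blood genes, 0 passed over all genes or adjusted over the list alone, and the largest log2 fold change was 0.72 for Runx1 (camera adjusted p = 0.136 for the list). Runx1 passed without control clone 2 (limma adjusted p = 0.0326) and had -0.46 with the fibroblast list mean as a covariate. Of 18 genes of the interferon response, 0 passed over all genes, while adjusted over the list alone 1 was higher and 2 were lower (camera adjusted p = 0.523). Oasl2, Ddx58 and Ifit2 had log2 fold changes of 0.65, -0.63 and 0.56 with limma adjusted p-values of 0.0709, 0.0831 and 0.138. Oasl2 passed with array weights (0.0472) and Ddx58 among brighter genes alone (0.0496). Of 7 genes of the 2-cell-like state, a rare state of embryonic stem cells, 0 passed in either adjustment (camera adjusted p = 0.509). Usp17la read 5.70 in control clone 3 and between 3.34 and 3.73 in the other 5 clones, and Tdpoz1 4.09 to 4.30 in the control clones and 3.30 to 4.21 in the shECAD clones. Zfp352 had a log2 fold change of 0.44, which was 0.23 without control clone 2 and 0.70 without control clone 3. In the list of Y-linked genes and Xist, with 4 members measured, 0 passed over all genes and 1, Xist, was higher adjusted over the list alone. Xist, the RNA of the inactive X chromosome, read 5.11 ± 0.74 (SD) in the control clones and 7.02 ± 1.04 in the shECAD clones (log2 fold change 1.91 ± 0.48 SE, limma adjusted p = 0.0609). It passed without control clone 2 (0.0392), without shECAD clone 9 (0.0176), with array weights (0.012) and with high Y-linked genes as a covariate (0.042), and its change was 0.35 with the fibroblast list mean as a covariate. That list was not called (camera adjusted p = 0.444), but was called without control clone 3 (0.00561). No other control clone had high Eif2s3y (8.45 in control clone 3), while shECAD clone 9 (7.95) stayed in. Leaving out control clone 3 thus raises the list by itself. The list's mean log2 fold change was 1.45 there and -0.18 without control clone 4.

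In all, camera with a preset correlation called 16 of 22 lists, 13 higher and 3 lower. With an estimated correlation it called 0, and 3 lists had an unadjusted p below 0.05, those of imprinted genes, mesenchymal transition, and hypoxia and glycolysis. The test fry, which asks whether a list moves on balance in one direction, called 4 lists, these 3 with that of actin and focal adhesion. Its mixed form, which counts changes in either direction, called 16. With the fibroblast list mean as a covariate camera called 8. This fit sets the mean change of the fibroblast list itself to 0, so the loss of that list's call says nothing about it. The other lists no longer called were those of mesenchymal transition, other cadherins and catenins, Wnt targets, Nodal and primed epiblast, endoderm, p53, and actin and focal adhesion.

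**Figure D3:**
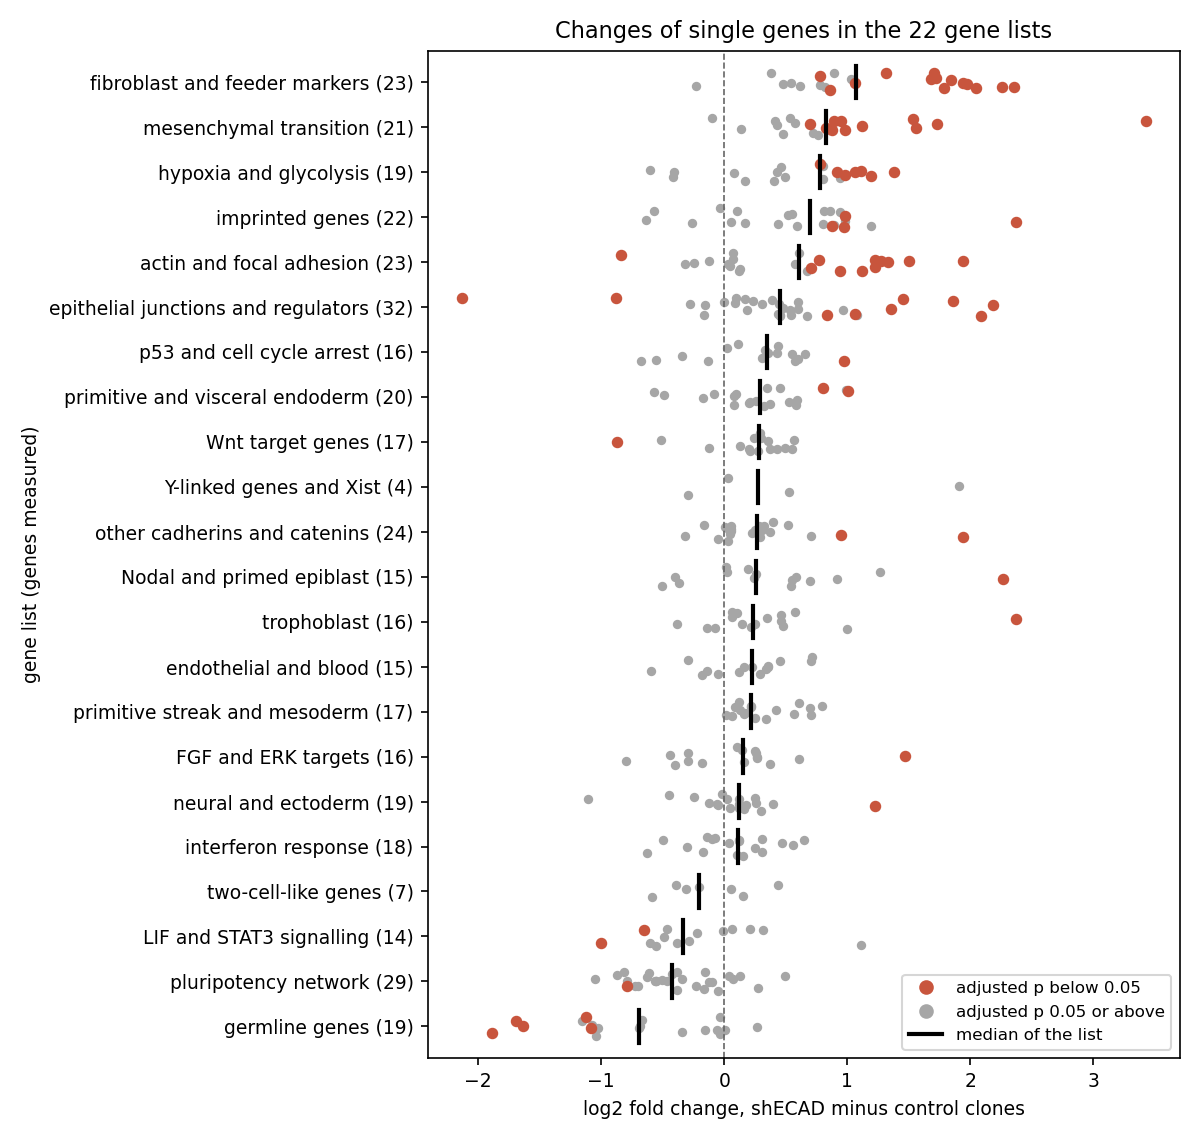
Log2 fold changes (horizontal axis, shECAD minus control) of the measured genes of the 22 lists, 1 point per gene with random vertical scatter, coloured where the limma adjusted p is below 0.05; black bars are list medians and numbers in brackets are genes measured. The list medians run from -0.70 for germline genes to 1.07 for fibroblast and feeder markers.

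The 2 groups of clones lay apart over the whole set of genes. The mean Euclidean distance was 65.6 between clones of different groups and 52.01 between clones of the same group, a difference of 13.59, which an exact permutation test gave a one-sided p of 0.1, the smallest the 10 splits allow. The ranges overlapped, since control clone 2 and shECAD clone 8 were 54.61 apart and shECAD clones 8 and 9 were 58.05 apart. On a principal component analysis, the component with the largest variance (46.8%) placed the control clones at -10.06, -35.94 and -26.57 and the shECAD clones at 17.85, 12.45 and 42.27. Pearson's r across genes, which are not independent replicates, ran from 0.958 for control clone 3 with shECAD clone 9 to 0.988 for shECAD clones 4 and 8.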

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

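The tests of the fibroblast and germline lists and the count of splits for genes were chosen after the results were seen, and the count of splits for gene lists was set before.

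Among the 5443 probesets with no gene name here, which the comparison by gene does not use, 14 passed a limma adjusted p of 0.05 when every probeset was tested on its own, 11 higher and 3 lower in the shECAD clones. Of the 1621 probesets with several gene names, 6 passed.

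The fibroblast and feeder list was higher in the shECAD clones, with a median log2 fold change of 1.07, and among its abundant members Col1a1 read 9.81 in the shECAD clones and 7.84 in the controls. A narrower range of values on the shECAD arrays would lower bright genes. In the 4th and 5th of 5 equal groups of genes by level the median log2 fold change was -0.0996 and -0.14. Of the list's 23 members, 17 lie above the median gene level in the control clones, and for these the rise itself argues against a narrower range. Quantile normalization, which gives all arrays the same range, could not have removed such a rise and adds no support. After it the median was 1.09 and the mean difference between clones was 1.27, with a 95% interval from 0.39 to 2.16. Camera at an estimated correlation did not call the list there (adjusted p = 0.188), and fry did (0.0461). Carry-over of feeder RNA, or of unreprogrammed fibroblasts, cannot be told apart from expression by the shECAD cells. With the mean of the other members held fixed, as 1 carried-over RNA of fixed profile would require, 4 of 23 members still differed between groups on the log2 scale, Thy1 and Postn upwards and Lum and Dcn downwards, but on the linear scale only 1, Lum. An effect of lower E-cadherin, which the design names, also stays open, and no test here separates it from carry-over.

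The germline list was lower in the shECAD clones, with a mean log2 fold change of -0.74. Without shECAD clone 9 the mean was -0.53, but with a 95% interval over clones from -1.15 to 0.09. The list means of shECAD clones 4 and 8, 5.17 and 5.22, both lay below the lowest control mean, 5.51, so clone 9 was not the only low clone. The interval includes no change, so that a fall in the group beyond clone 9 stays undecided. Without that clone, camera called the list at the preset correlation (adjusted p = 9.86e-06), but not at an estimated one (0.27), and fry did not (0.112). Dilution of iPS RNA by other cells cannot be told apart, because such dilution would also lower pluripotency genes, and the germline list fell beyond the pluripotency list by a difference of -0.37 with a 95% interval from -1.02 to 0.29. With the fibroblast list mean as a covariate the germline mean was -1.09, with an interval from -3.01 to 0.83. A difference between the groups in the regulation of germline genes was not tested.

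Chance in the assignment of clones was judged by the 10 splits of the 6 clones into groups of 3, which are too few for a share under 0.05. In 1 of them, the real one, 623 genes passed, and the highest of the other splits gave 0 genes. Each other split has clones of both groups on each side, so a difference between the groups adds to the spread within the sides. The count of 0 is therefore no measure of what chance alone would give. For gene lists, the real split gave 16 called lists, reached in 1 of the splits, and each of the others gave between 5 and 11. Camera at the preset correlation thus also called lists in every split that mixes the groups. These splits hold unequal numbers of clones of the 2 groups on each side, so part of a group difference remains in them.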

How the results depend on the processing

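The 2 covariate fits were chosen after the data were seen, the other settings before. Cdh1 stayed lower in all settings (-1.92 to -2.45 with a clone left out) and stayed called except without variance moderation (-2.13, adjusted p = 0.194) and with the fibroblast list mean as a covariate (-2.23, adjusted p = 0.998); its adjusted p ranged from 0.00168 to 0.998. The count of changed genes, 623, lay between 545 and 819 under median centring, quantile normalization, the dim-gene filter, averaged probesets and the trend, and was 525 with the Y-linked covariate. It was 1067 with array weights, 241 with every probeset on its own and 1278 at an adjusted p below 0.1. Without moderation, which leaves few degrees of freedom per gene, it was 3 (Bbs1, Pold1 and Slc35f5, chosen after their values were seen), with 2972 at an unadjusted p below 0.05. With the fibroblast covariate it was 0. With a clone left out it ranged from 146 to 543, with fewer samples. All 623 genes kept their sign in these model fits where tested, except under the fibroblast covariate, where 608 did and 15 did not, of which 2, Prrx1 (-0.16) and Ankrd1 (-0.017), are named genes. The cause was not tested.

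The number of called lists, 16, was 12 to 16 in the planned camera fits and 13 to 16 with a clone left out. It was 8 with the fibroblast covariate, which sets the mean change of the fibroblast list to 0 and so removes that list by construction, 0 with an estimated correlation and 4 with fry, and the cause was not tested. The group separation of 13.59 was 11.23 to 16.71 with a clone left out and positive in every setting run. Of the 61 named genes that were called, 28 kept their call with each clone left out in turn. Over the planned model fits with all 6 clones, where tested, 0 kept it, and 52 did once the fit without moderation was set aside. The fit of brighter genes alone tested 56 of the 78 named genes besides Cdh1. The test of every probeset on its own, which called fewer, is not part of this count. No paired analysis was possible because the labels pair no control clone with a shECAD clone. The number 4 occurs in both groups but names separate cell lines. Dim genes are limited by signal over background, and no detection call was used. The median log2 fold change ran from 0.12 to -0.14 over 5 equal groups of genes by level, and lay between -0.036 and 0.0092 after quantile normalization.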

Other observations

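Single clones differed from the others in genes that the comparison of groups does not single out, and the genes of this paragraph were chosen after their values were seen, apart from Xist, Eif2s3y and Kdm5d. The Y-linked genes Eif2s3y and Uty were high in 1 clone of each group. Eif2s3y read 8.45 in control clone 3 and 7.95 in shECAD clone 9 and between 3.04 and 4.82 in the other clones, and Uty read 7.65 and 6.80 there and between 2.91 and 4.05 elsewhere. Kdm5d, also Y-linked, read 6.04 in control clone 3 but 4.91 in shECAD clone 9, which is below the median of that array (5.30), and between 3.55 and 4.39 elsewhere. Xist read 7.88 and 7.31 in shECAD clones 4 and 8, and between 4.42 and 5.89 in the others, shECAD clone 9 included.

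Meg3 and Rian, maternally expressed non-coding RNAs of the imprinted Dlk1 locus, were low in control clone 3, with log2 values of 7.15 and 5.25. In the other 5 clones Meg3 read 8.81 to 9.52 and Rian 6.99 to 7.37. The imprinted growth factor gene Igf2 read 6.17 to 7.82 in the control clones and 8.25 to 8.31 in the shECAD clones (log2 fold change 1.19, limma adjusted p = 0.0834).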
